A study of Mus musculus with 69 samples.

How the data were processed

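Bone marrow-derived macrophages of wild-type mice were studied, per the labels and the series design. Each of 5 biological replicates was pooled from 6 mice. Marrow cells were grown in M-CSF, the growth factor that drives macrophage differentiation, at 50 ng/mL, harvested on day 7, frozen and later thawed for editing. Cas9 ribonucleoprotein, a complex of the Cas9 nuclease with a guide RNA, was directed at Rosa26, a locus used as the editing control, or at Atp6v1a, Npc1, Pik3c3, Ctsd, Grn or Trem2. The sample labels give the time of collection in hours and the series design gives the same numbers as days. Days are used here. The 69 libraries fall into 14 groups of 1 target and 1 time (day 4 or day 13 after editing), with n = 5 in each group except Npc1 at day 4, where n = 4 (replicates 2 to 5).

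The authors made 3' tag libraries (QuantSeq with unique molecular identifiers) and sequenced them as 75 bp single-end reads, per the labels' protocols. Such libraries read the 3' end of each message, so a level in this assay says little about where along the gene an edit lies, and small insertions or deletions need not remove the 3' reads. A label divides the libraries into 47 made with a Regular and 22 made with a Low-input protocol. How the protocols differ is not given in the sources used here. RNA integrity numbers in the labels run from 8.6 to 10 and are missing for 4 libraries. The deposited table of estimated counts was made with Salmon on GRCm39, per the submitters' processing notes, and the version of Salmon is not given in the sources used here. The estimated counts are not whole in 31.2% of the values above 0 and were rounded to whole numbers for the tests. A deposited table of log2 CPM (counts scaled to the library total), made by the authors from the same libraries, served for gene symbols and as a check. It differed from log2 CPM computed here by a median of 0.012 and at most 0.117. All columns of libraries were matched to samples by their names. The reference genome at hand is GRCm38, another build, so no coordinates are given, and it was used only for transcript sequences and gene positions in 1 check.

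Totals ran from 2194566 to 4688285 counts per library with a median of 3404743. No library was shallow enough to meet the planned exclusion. Of 56980 genes, 12008 passed edgeR's filterByExpr by group and were tested. Among tested genes, 12 symbols belong to several gene identifiers. Estimated counts of near-identical genes, such as the globin and MHC genes, can be divided between copies by the quantification, so the level of a single copy is uncertain. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of 1.734 to 72.209 between libraries of the same group.

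Tests used R 4.3.3, edgeR 4.0.16 and limma 3.58.1. All 69 libraries entered a single edgeR quasi-likelihood fit (TMM scaling, 1 mean per group and a term for library protocol), so that all groups share an estimate of the spread. Two-sided tests compared each targeted group with Rosa26 cells of the same day, compared these effects between days, and compared Rosa26 cells of the 2 days. P-values were adjusted by Benjamini-Hochberg over the 12008 genes of a comparison, and a gene was called at an adjusted p under 0.05. Changes are log2 fold changes ± SE from this fit, in which the protocol difference has been removed. The SE was derived as the absolute change divided by the square root of the test's F statistic. For genes with few counts it is only a rough measure of spread. Group levels are mean CPM ± SD and keep the protocol difference, so the 2 measures can differ where a group mixes protocols. On simulated counts of 11789 genes with 200 genes changed, the fit recovered 87% of 2-fold and 99% of 4-fold changes for Npc1 at day 4, with 6 false among 192 calls. For Grn at day 13 it recovered 90% and 100%, with 11 false among 201 calls. For Trem2 at day 13 it recovered 85% and 99%, with 9 false among 193 calls.

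A total of 29 gene lists was fixed before the data were examined, as were the comparisons, the fit used for all results, the rule for named genes and most of the other settings tried. The lists cover sterol synthesis and uptake (SREBP2 targets), LXR targets, fatty acid synthesis, V-ATPase subunits, lysosomal hydrolases, lysosomal membrane and transport proteins, autophagy, TFEB and nutrient sensing, interferon-stimulated genes, NF-kB inflammatory genes, lipid-associated macrophage genes, the integrated stress response, the unfolded protein response, hypoxia and glycolysis, iron handling, the cell cycle, p53 targets, NRF2 targets, macrophage identity, MHC class II presentation (called MHC class II for short, with the regulator Ciita and the costimulatory gene Cd86 among its members), immediate early genes and mitochondrially encoded messages, and markers of neutrophils, dendritic cells, lymphocytes, stromal cells, erythroid cells, osteoclasts and mast cells or basophils. No member of the dendritic cell and lymphocyte lists passed the filter, and the mast cell list kept 1 gene, Kit. Each list was counted by its called members, also with p-values adjusted over the list alone, and tested with limma's camera at a preset correlation of 0.01. The p given as "with an estimated correlation" is camera's adjusted p over all list tests of a comparison when the correlation between genes is estimated from the data. Of 513 list tests, 190 passed at the preset and 105 with an estimated correlation, and all 105 were among the 190.

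Named genes are the targeted gene, the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean of at least 5 CPM in a compared group and the same direction in at least 4 of the 5 same-numbered pairs (3 where only 4 pairs exist), and up to 3 called members of each list with the smallest p. For differences between days and for Rosa26 cells over time these numbers are 5, 5 and 2. Genes with clone-style names were left out. From this selection the text gives part, and some single genes are not reported here. Where fewer than 3 genes were called, the next genes by p are named and said not to pass. Unless another number is given, each called gene named against Rosa26 cells or over time moved in the stated direction in all same-numbered pairs, compared after the protocol effect was removed from log2 CPM. Genes named as shared between targets were not held to this.

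Same-numbered libraries come from the same pool of marrow, per the series design. Their deviations from the group means correlated by a mean of 0.02 to 0.16 across comparisons, against -0.04 to -0.01 for other numbers. The replicate number was not a term of that fit, and a fit with it as a block is among the alternatives. Settings fixed then were DESeq2 1.42.0, RLE size factors, no filter on low counts, no protocol term, the replicate block, Regular libraries only, each day fitted separately, leaving out each library and each replicate number, an estimated correlation or limma's fry for the lists, and splitting the Rosa26 libraries into 3 and 2 for shared calls. Added after the data were seen were Low-input libraries only, a fit without Rosa26 replicates 2 and 5 of day 13, and the summed level of brain markers of each library as a covariate. For that sum, 27 markers of neurons, oligodendrocytes and astrocytes were written down before their values were looked at but after other brain genes had been noticed. The sum holds the 24 with under 10 CPM in Rosa26 cells of day 4, a limit set after the values of the others (Npy, Uchl1 and Syn1) were seen. Shared calls were set beside 100 simulations of unchanged groups that share the Rosa26 libraries and beside 20 splits of those libraries.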

Results

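Gene expression was measured in mouse bone marrow-derived macrophages 4 or 13 days after Cas9 editing of Atp6v1a (subunit A of the V-ATPase proton pump that acidifies lysosomes), Npc1 (the lysosomal cholesterol exporter), Pik3c3 (the class III lipid kinase of autophagy and endosomal traffic), Ctsd (the lysosomal protease cathepsin D), Grn (progranulin) or Trem2 (a lipid-binding surface receptor). Cells edited at Rosa26 were the control. The data comprise 69 libraries of 3' tags in 14 groups, each with n = 5 except Npc1 at day 4 with n = 4. Library totals lay between 2194566 and 4688285 counts. Changes below are log2 fold changes ± SE against Rosa26 cells of the same day, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

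The targeted gene was examined first in every group. Each of the 12 targeted groups had less of its targeted message than Rosa26 cells, in all same-numbered pairs once the protocol effect was removed. Ctsd (ENSMUSG00000007891.17) stood at 797 ± 93 CPM in Ctsd-targeted cells of day 4 against 4056 ± 151 CPM (SD, n = 5 each), a change of -2.35 ± 0.07, and changed by -2.25 ± 0.08 at day 13. Grn (ENSMUSG00000034708.13) changed by -2.26 ± 0.15 at day 4 and -2.54 ± 0.15 at day 13, when it stood at 474 ± 51.6 against 2800 ± 316 CPM. Npc1 (ENSMUSG00000024413.15) changed by -1.60 ± 0.18 and -1.55 ± 0.17, with 29.3 ± 5.83 CPM (n = 4) against 88.9 ± 5.18 CPM at day 4. Atp6v1a (ENSMUSG00000052459.14) retained 56% of the Rosa26 level at day 4 and 73.5% at day 13 (-0.84 ± 0.08 and -0.44 ± 0.08). Pik3c3 (ENSMUSG00000033628.16) retained 59.4% and 68% (-0.75 ± 0.11 and -0.56 ± 0.11). Trem2 (ENSMUSG00000023992.15) retained 30.5% at day 4 (-1.71 ± 0.13) and 56% at day 13 (-0.84 ± 0.14). Adjusted p-values lay between 1.36e-37 for Ctsd at day 4 and 0.00012 for Pik3c3 at day 13. The effect on the targeted gene differed between days for Atp6v1a (difference 0.39, adjusted p = 0.0101) and Trem2 (0.88, adjusted p = 0.00109). Without a term for library protocol the Trem2 value of day 13 was -0.28 (adjusted p = 0.257), and the Atp6v1a difference between days was 0.25 (adjusted p = 0.377). The Pik3c3 value of day 13 was -0.35 in Regular libraries, with 1 Pik3c3 library, and -0.52 in Low-input libraries, with 1 Rosa26 library. Neither passed, but a group of 1 library limits both tests. Because 3' tags can persist after small insertions or deletions, these levels neither prove nor exclude editing in a cell.

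**Figure D1:**
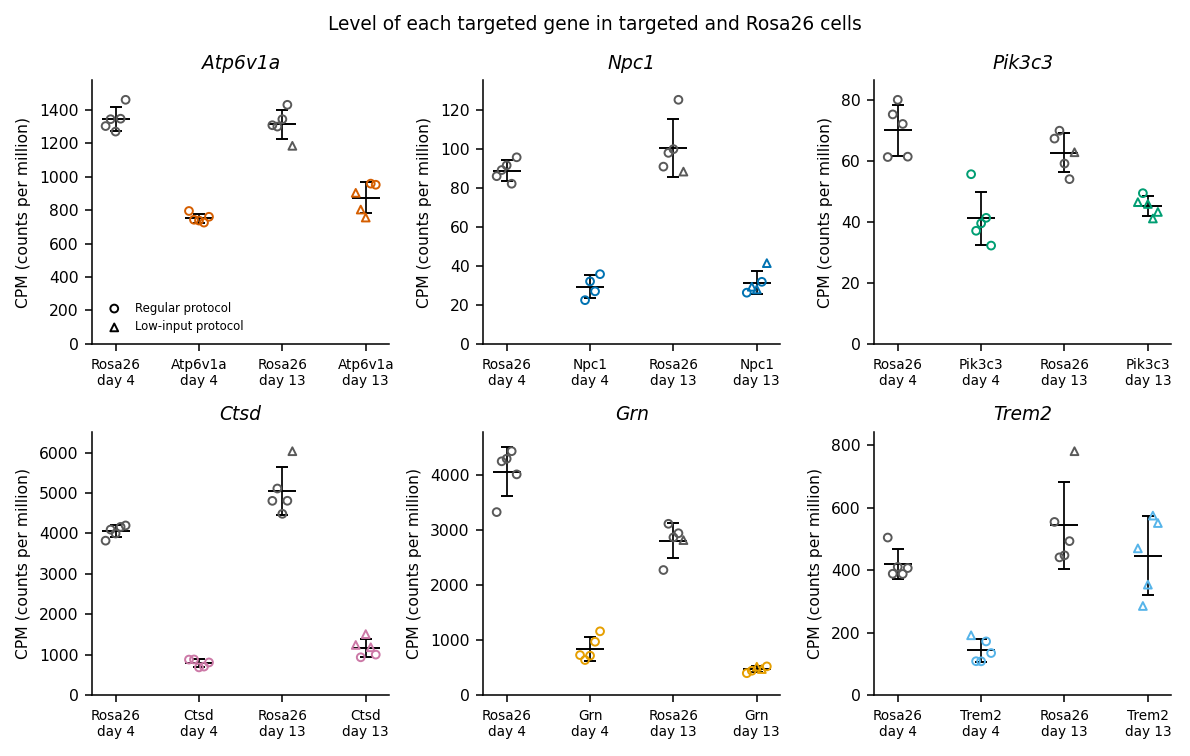
Level of each targeted gene in CPM (vertical axis, from 0) in Rosa26 and targeted cells of day 4 and day 13; points are libraries (circles Regular, triangles Low-input protocol), horizontal bars group means and error bars SD. Ctsd stood at 797 ± 93 CPM in Ctsd-targeted cells of day 4 against 4056 ± 151 CPM in Rosa26 cells, while the Trem2 libraries of day 13 overlapped those of Rosa26 cells in CPM.

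Library protocol was unevenly spread over the groups. At day 4 only Trem2 replicate 1 was Low-input, whereas at day 13 all 5 Trem2 libraries, 4 Pik3c3, 3 Atp6v1a, 3 Npc1, 3 Ctsd, 2 Grn and 1 Rosa26 library (replicate 5) were. Between protocols 8043 of the 12008 genes differed, with 4185 higher and 3858 lower in Low-input libraries. Malat1, a nuclear noncoding RNA, stood at 2359 ± 456 CPM in the 47 Regular and 174 ± 70 CPM in the 22 Low-input libraries, and Regular libraries detected 18815 ± 686 genes against 17544 ± 636. The first principal component held 31.9% of the variance and set the protocols apart. After the protocol effect was removed, it held 25.6% and set the days apart, and the next component, with 12.9%, set the Trem2 libraries of both days apart from the others. Within day 13, Low-input comparisons rest on a single Rosa26 library, and no Regular Trem2 library exists at that day, so Trem2 has no Regular-only value there.

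**Figure D2:**
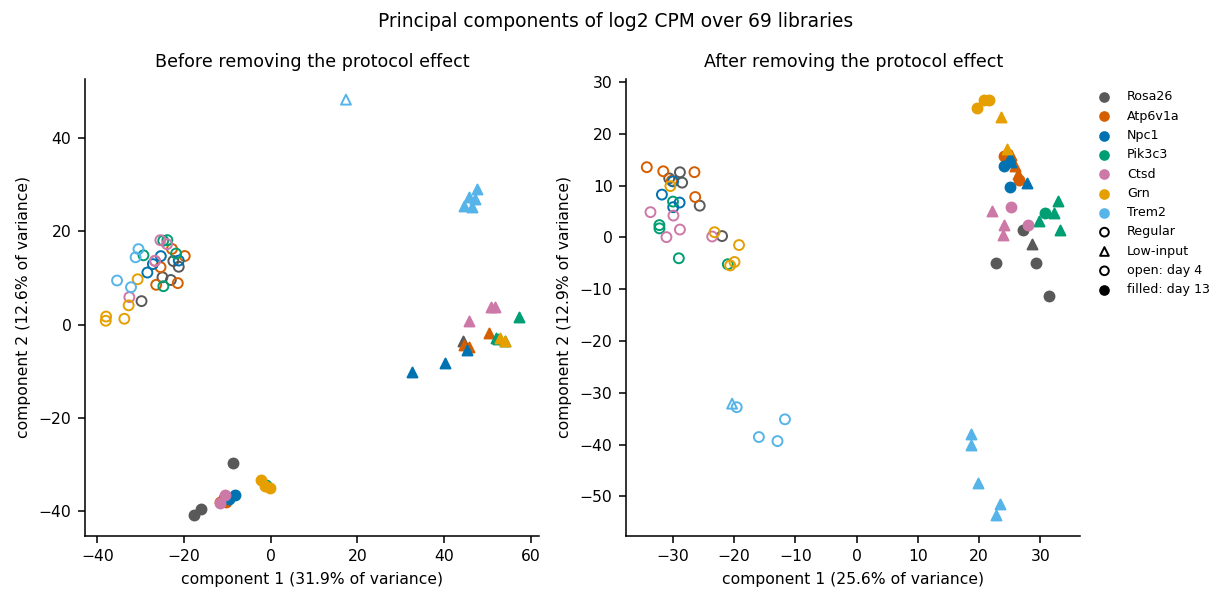
First 2 principal components of log2 CPM over 69 libraries before (left, 31.9% and 12.6% of the variance) and after (right, 25.6% and 12.9%) removal of the protocol effect; colours are targets, circles Regular and triangles Low-input libraries, open symbols day 4 and filled symbols day 13. Low-input and Regular libraries lie apart on the left, and days and Trem2 libraries lie apart on the right.

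Messages of other cell types also differed between groups. The summed level of 24 brain markers, which macrophages are not known for, was 41.6 ± 14.8 CPM in Rosa26 cells of day 4, 122 ± 23.1 in Grn cells and 168 ± 76.3 in Trem2 cells of day 4, and between 32.6 and 52.3 in the other groups of that day. At day 13 it was 132 ± 65.4 CPM in Rosa26 cells, 28.3 ± 1.72 in Grn cells and between 39.5 and 67.1 in the others. Among day 13 libraries outside the Grn group, it ran from 13 to 63.4 CPM with the Low-input and from 79.6 to 208 CPM with the Regular protocol. Haemoglobin messages moved with these markers. After removal of the protocol effect, stromal markers (Col1a1, Col1a2 and Sparc) had a mean log2 CPM of 4.6 and 6.25 in Rosa26 replicates 2 and 5 of day 13. It was 1.49 to 1.73 in the other 3. Replicate 5 is Low-input, so its value depends on that removal. Of 13 mitochondrially encoded messages, mt-Nd4l rose in Npc1 and Pik3c3 cells of day 13 (0.36 ± 0.11 and 0.41 ± 0.11) and mt-Co1 and mt-Cytb in Trem2 cells of day 13 (0.35 ± 0.12 and 0.33 ± 0.12). None of these 4 rises kept its call in Low-input libraries alone. Rosa26 replicate 5 is the only control there, so these losses cannot tell protocol from group size. Without single libraries mt-Nd4l lost its call in Npc1 cells (Rosa26 replicate 3, 4 or 5 or Npc1 replicate 5, adjusted p between 0.0763 and 0.204). In Trem2 cells mt-Co1 lost it (Rosa26 replicate 2, 3 or 4 or Trem2 replicate 1, 0.069 to 0.137). So did mt-Cytb there (any of Rosa26 replicates 2 to 5 or Trem2 replicate 1, 0.0765 to 0.152).

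Calls were few at day 4 for 4 of the targets and numerous for the other two. At day 4, 1 gene was called in Atp6v1a cells, 1 in Npc1, 21 in Pik3c3, 15 in Ctsd, 966 in Grn and 2912 in Trem2 cells. At day 13 the counts were 2927, 536, 1587, 24, 3028 and 2666 in the same order. Calls over 2-fold numbered 0, 1, 7, 8, 253 and 822 at day 4 and 567, 75, 410, 19, 581 and 670 at day 13.

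**Figure D3:**
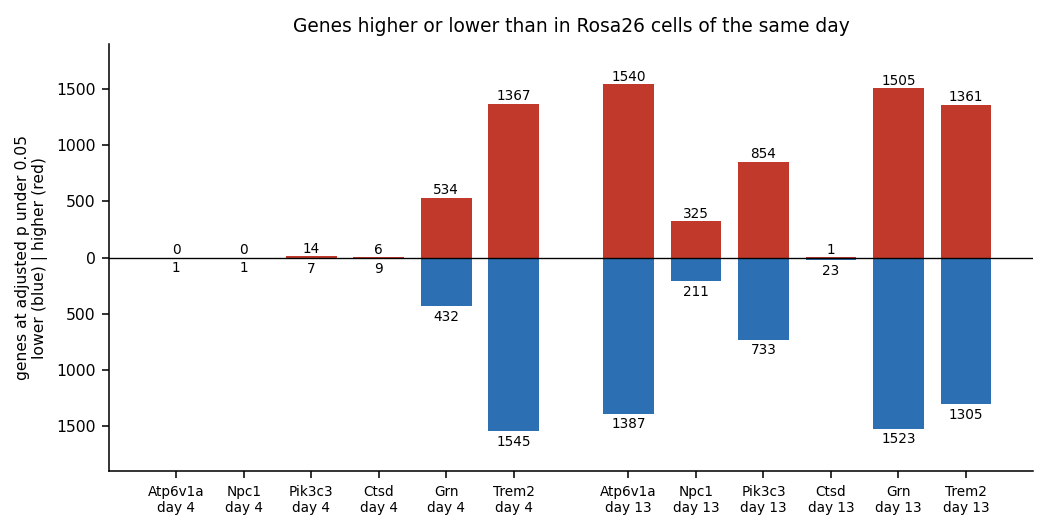
Number of genes higher (red, above 0) and lower (blue, below 0) than in Rosa26 cells of the same day at an edgeR adjusted p under 0.05, by target and day. Trem2 cells had 1367 higher and 1545 lower genes at day 4, and Ctsd cells 1 higher and 23 lower at day 13.

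The question at day 4 was which genes respond early to loss of each target. In Atp6v1a and Npc1 cells the targeted gene was the only call (Atp6v1a -0.84 ± 0.08, adjusted p = 3.01e-12; Npc1 -1.60 ± 0.18, adjusted p = 1.23e-08). The genes next by p did not pass: Gpr107 at -1.12 ± 0.25 (adjusted p = 0.234) in Atp6v1a cells, and Gpr107 at -1.09 ± 0.27 and Tnfrsf26 at 0.81 ± 0.21 (both adjusted p = 0.694) in Npc1 cells. No member of the 24 sterol synthesis and uptake genes was called in either group, over all genes or adjusted over the list alone. Their median was 0.12 in Atp6v1a and 0.11 in Npc1 cells, and camera's call (adjusted p = 0.00901 and 0.000354) was lost with an estimated correlation (adjusted p = 0.314 and 0.171). The unadjusted p was under 0.05 for 259 genes in Atp6v1a and 464 in Npc1 cells, and DESeq2 called 5 and 3. Leaving out Rosa26 replicate 2, 3, 4 or 5 gave 2 calls in Atp6v1a cells, Gpr107 being the other (adjusted p between 0.0159 and 0.0186). In Rosa26 cells of day 4 Gpr107 stood at 137.9 ± 163.8 CPM, an SD above the mean. Its calls in Pik3c3 and Ctsd cells of that day rest on Rosa26 replicate 1.

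In Pik3c3 cells of day 4, 14 genes rose and 7 fell. Marco, a scavenger receptor, rose by 2.36 ± 0.44 (adjusted p = 0.00282), Acod1, which makes the antimicrobial metabolite itaconate, by 1.63 ± 0.32, and Saa3, an acute phase protein, by 1.5 ± 0.32. The lectin Mgl2 (1.24 ± 0.3, adjusted p = 0.0488) and F13a1, subunit A of clotting factor XIII (0.88 ± 0.21), rose as well. Gclm, a subunit of the enzyme for glutathione synthesis, rose by 0.54 ± 0.1 (adjusted p = 0.00141) and was the only called gene among 16 NRF2 targets, with 4 higher when adjusted over the list alone (adjusted p = 0.00405 with an estimated correlation). Dcstamp, needed for cell fusion, fell (-1.24 ± 0.22), as did Chst11, a sulfotransferase (-0.95 ± 0.17). No sterol gene and no MHC class II gene was called over all genes; adjusted over the list alone 7 of 24 sterol genes were higher and 2 of 8 MHC class II genes lower (adjusted p = 0.0157 and 0.0173 with an estimated correlation). Marco and Dcstamp kept their calls without any 1 library, whereas Mgl2, F13a1, Saa3 and Acod1 did not, with Acod1 at adjusted p = 0.0596 without Pik3c3 replicate 3. The call of Gpr107 (-1.22 ± 0.26) rests on Rosa26 replicate 1, without which its adjusted p was 0.825. The number of calls was 42 with the replicate block and 34 by DESeq2, and 12, 11, 12 and 11 without Rosa26 replicate 1, Rosa26 replicate 3, Pik3c3 replicate 3 and Pik3c3 replicate 4.

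Ctsd cells of day 4 had 6 higher and 9 lower genes, Ctsd among the latter. Ifi205, an interferon-inducible gene, rose by 1.63 ± 0.37 (adjusted p = 0.0394), Mgl2 by 1.27 ± 0.3 (adjusted p = 0.0442), Ms4a6d by 0.55 ± 0.11 (adjusted p = 0.0096), and the fucosidase Fuca2 and the LXR target Smpdl3a by 0.47 ± 0.1 and 0.37 ± 0.08. The olfactory receptor gene Olfr46 fell by 2.12 ± 0.37 (adjusted p = 0.000979), and Tmem176a and Tmem176b, a pair of related membrane protein genes, changed by -0.68 ± 0.14 and -0.66 ± 0.14. None of 35 interferon-stimulated genes was called over all genes and 8 were higher when adjusted over the list alone. Their median was 0.33, and camera's call was lost with an estimated correlation (adjusted p = 0.124). Ctsd was the only called gene of the lysosomal hydrolase list, which holds neither Fuca2 nor Smpdl3a. Leaving out single libraries ended the calls of Ifi205, Mgl2, Ms4a6d, Fuca2, Smpdl3a, Tmem176a and Tmem176b but not that of Olfr46, and Gpr107 (-1.19 ± 0.26, 4 of 5 pairs) again rested on Rosa26 replicate 1 (adjusted p = 0.842 without it). The count was 34 with the replicate block and 29 by DESeq2, and 8, 8, 6, 5 and 9 without Rosa26 replicate 2, Rosa26 replicate 4 and Ctsd replicates 1, 2 and 4.

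In Grn cells of day 4, 534 genes rose and 432 fell. Of 24 sterol synthesis and uptake genes 11 rose (13 adjusted over the list alone; adjusted p = 0.00846 with an estimated correlation), among them the synthase Hmgcs1 by 0.86 ± 0.1 (adjusted p = 2.43e-09) and the SREBP regulator Insig1 by 0.89 ± 0.17. LXR targets moved both ways, with 3 of 12 higher and 4 lower. The desaturase Scd2 rose by 1.37 ± 0.18, and the lipid carriers Pltp and Apoe fell (-0.96 ± 0.11 and -0.96 ± 0.16). Of 19 macrophage identity genes 2 rose and 9 fell (adjusted p = 0.00165 with an estimated correlation), including the chemokine receptor Cx3cr1 by -1.72 ± 0.24 (adjusted p = 5.8e-07) and Adgre1, which encodes F4/80, by -0.55 ± 0.1. MHC class II fell in 3 of 8 genes (adjusted p = 0.00921 with an estimated correlation), with Cd74 and H2-Ab1 at -1.98 ± 0.32 and -1.98 ± 0.41. Tmem176a (-1.59 ± 0.14) and Dcstamp (-1.59 ± 0.23) fell too. Interferon-stimulated Mx1 (1.29 ± 0.3) and Ifit2 (1.36 ± 0.36) were 2 of 5 higher genes of 35, a list call lost with an estimated correlation (adjusted p = 0.254). Among the largest rises were Thbs1 (2.33 ± 0.53), Ndrg2 (2.24 ± 0.31), the synaptic gene Cplx2 (2.48 ± 0.49) and haemoglobin Hbb-bs (2.37 ± 0.46), with all 3 erythroid genes higher. In these cells the brain markers stood at 122 ± 23.1 against 41.6 ± 14.8 CPM. With that level as a covariate, added after the data were seen, 883 genes were called, 543 of them in both fits, and Cplx2 (0.72, adjusted p = 0.448) and Hbb-bs (0.82, adjusted p = 0.425) were not. Ndrg2, whose level followed the brain markers, stood at 0.8 in that fit (adjusted p = 0.0377). Of the 131 called genes that rose with the marker level in that fit, 122 lost their call there. The same fit picked these genes and judged their calls, and the marker level partly follows the groups, so such losses were favoured in advance. Without Grn replicate 3 the count was 629, and without the protocol term 300. All Grn and Rosa26 libraries of day 4 are Regular, so that term can change the count only through the spread that all groups share.

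Trem2 cells of day 4 had 1367 higher and 1545 lower genes. F13a1 rose by 3.31 ± 0.19 (adjusted p = 1.6e-22) to 112 ± 23.3 from 10.8 ± 1.91 CPM, and Ripor2 and the purinergic receptor P2ry13 rose by 3.27 ± 0.34 and 3.09 ± 0.3. Of 23 lipid-associated macrophage genes 19 fell (19 adjusted over the list alone, adjusted p = 4.11e-06 with an estimated correlation), including Itgax, which encodes CD11c, by -3.61 ± 0.3, the fatty acid binder Fabp4 by -2.83 ± 0.28 and the elastase Mmp12 by -2.67 ± 0.19. The targeted gene Trem2 is itself on this list and counts among the 19. Dcstamp (-3.95 ± 0.31), Slamf8 (-3.01 ± 0.23) and the interleukin-1 receptor antagonist Il1rn (-2.87 ± 0.2) fell. Sterol genes fell in 12 of 24 cases (Cyp51 -1.12 ± 0.15, Srebf2 -0.88 ± 0.14; adjusted p = 0.0478 with an estimated correlation). Of 23 hypoxia and glycolysis genes 14 fell and 2 rose (adjusted p = 0.0176 with an estimated correlation), among them Aldoa by -0.72 ± 0.08, the glucose transporter Slc2a1 by -1.18 ± 0.14 and the lactate exporter Slc16a3 by -1.54 ± 0.2. Immediate early genes fell in 6 of 12 cases and rose in 1, with Egr1 at -2.05 ± 0.2, Zfp36 at -1.77 ± 0.15 and Dusp1 at -1.58 ± 0.16 (adjusted p = 0.00395 with an estimated correlation). MHC class II fell in 5 of 8 genes (Cd74 -2.49 ± 0.34, H2-Ab1 -2.60 ± 0.44). Macrophage identity genes went both ways, 7 higher and 6 lower of 19, with Mrc1, the mannose receptor, at 1.24 ± 0.13, Maf at 0.90 ± 0.09 and Cx3cr1 at -2 ± 0.24. All 3 erythroid genes were higher (Hba-a2 2.94 ± 0.46, Hbb-bs 2.80 ± 0.45), and brain markers stood at 168 ± 76.3 CPM, with 37.3 in replicate 1, the only Low-input library. Of 3 stromal genes Sparc rose (1.99 ± 0.56, adjusted p = 0.0049), and 4 of 13 mitochondrially encoded messages rose (mt-Nd5 0.47 ± 0.11), a list call lost with an estimated correlation (adjusted p = 0.502). With the brain-marker level as a covariate, 1922 genes were called, 1553 of them in both fits, and Hba-a2 (0.9), Hbb-bs (0.64), Sparc (1.07) and mt-Nd5 (0.28) were not.

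At day 13 the same comparisons addressed the later state of the cells. In Atp6v1a cells 1540 genes rose and 1387 fell. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose by 4.9 ± 0.2 (adjusted p = 2.94e-31) to 380 ± 92.7 from 15.8 ± 6.22 CPM, the thyroid hormone deiodinase Dio2 by 3.70 ± 0.18, Bex1 by 3.67 ± 0.36, the lectin Clec4e by 3.17 ± 0.23 and the receptor kinase Kit by 3.11 ± 0.43. The integrated stress response rose, with 21 of 26 genes higher and none lower (22 higher and 1 lower adjusted over the list alone; adjusted p = 7.92e-09 with an estimated correlation). Its members included Chac1 (2.89 ± 0.42), Trib3 (2.68 ± 0.2), the transcription factor Ddit3 (2.02 ± 0.14) and the seryl-tRNA synthetase Sars (1.39 ± 0.1). Of 18 V-ATPase subunits 11 rose, with Atp6v1c1 at 1.05 ± 0.08 and Atp6v0d1 at 0.67 ± 0.07, and 1 fell, the targeted gene Atp6v1a itself. Of 14 TFEB and nutrient-sensing genes 6 rose and 1 fell, with the GTPase Rragd at 1.49 ± 0.13. With an estimated correlation the adjusted p-values of these lists were 0.0139 and 0.00422. Sterol genes rose in 12 of 24 cases (Mvd 1.95 ± 0.17, Insig1 1.33 ± 0.18), unfolded protein response genes in 8 of 18 and hypoxia genes in 12 of 23, with 1 lower (adjusted p = 0.0496, 0.0219 and 0.0224 with an estimated correlation). All 8 MHC class II genes fell (H2-Eb1 -4.39 ± 0.37, H2-Ab1 -3.73 ± 0.29, Cd74 -3.28 ± 0.29), 14 of 19 macrophage identity genes fell and 1 rose (Maf -0.96 ± 0.09, Adgre1 -0.99 ± 0.1), and 8 of 12 LXR targets fell and 1 rose (Pltp -1.20 ± 0.11, Lpl -1.21 ± 0.14, Apoe -1.44 ± 0.17). The 3 stromal genes fell too (Col1a1 -6.22 ± 0.79), against the Rosa26 group that holds replicates 2 and 5. Of 3 erythroid genes Hbb-bs fell (-1.53 ± 0.45, adjusted p = 0.00785, and 0.0696 with the brain-marker covariate). Mitochondrially encoded messages fell in 7 of 13 cases and rose in 1 (mt-Atp6 -0.48 ± 0.11), a list call lost with an estimated correlation (adjusted p = 0.38). The count was 2061 in Regular libraries and 977 in Low-input libraries alone, where 11 integrated stress response genes and 5 MHC class II genes were called.

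Npc1 cells of day 13 had 325 higher and 211 lower genes. Of 24 sterol synthesis and uptake genes 13 rose and none fell (15 adjusted over the list alone; adjusted p = 2.59e-05 with an estimated correlation). The sterol enzyme Sqle rose by 1.10 ± 0.14 (adjusted p = 2.03e-07) to 50.3 ± 9.14 from 24.9 ± 2.53 CPM, and the sterol enzyme Mvd by 0.98 ± 0.18. The cholesterol exporter Abca1 fell by 0.74 ± 0.17, the only called gene of 12 LXR targets (adjusted p = 0.0844 with an estimated correlation). V-ATPase subunits rose in 9 of 18 cases (Atp6v1b2 0.45 ± 0.09, Atp6v1c1 0.38 ± 0.08; adjusted p = 0.00259 with an estimated correlation), and Fabp4 and the phosphatase Dusp2 rose by 1.42 ± 0.21 and 1.67 ± 0.34. Macrophage identity genes fell in 6 of 19 cases (Cx3cr1 -1.68 ± 0.23, Adgre1 -0.49 ± 0.1) and MHC class II in 4 of 8 (H2-Ab1 -1.01 ± 0.23, H2-Eb1 -1.02 ± 0.27; adjusted p = 0.0162 with an estimated correlation). H2-Eb1 lost its call without Rosa26 replicate 5 or Npc1 replicate 5. All 3 stromal genes fell (Col1a1 -5.66 ± 0.76, 4 of 5 pairs), as in Atp6v1a cells. The count was 101 in Regular and 82 in Low-input libraries alone, 353 without Rosa26 replicate 4, 318 without Npc1 replicate 5 and 341 with the brain-marker covariate. Sterol calls numbered 10 in Regular and 4 in Low-input libraries. No MHC class II gene was called within either protocol alone, and V-ATPase calls numbered 3 in Regular and 0 in Low-input libraries.

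In Pik3c3 cells of day 13, 854 genes rose and 733 fell. The chemokine Ccl5 rose by 5.02 ± 0.47, Cdkn1c by 4.68 ± 0.2 (adjusted p = 2.16e-29) to 292 ± 72.9 CPM, and Acod1 by 4.67 ± 0.36. Of 24 sterol genes 21 rose (21 adjusted over the list alone; adjusted p = 8.74e-09 with an estimated correlation), among them Mvd by 2.63 ± 0.17 and Sc5d by 1.59 ± 0.11, and 5 of 10 fatty acid synthesis genes rose (Acss2 3.46 ± 0.27, Fasn 1.19 ± 0.19; adjusted p = 8.23e-06 with an estimated correlation). NRF2 targets rose in 12 of 16 cases and fell in 1 (adjusted p = 4.01e-10 with an estimated correlation), with the cystine transporter Slc7a11 at 3.64 ± 0.23 (43.6 ± 4.19 against 3.68 ± 1.21 CPM), Gsta3 at 3.63 ± 0.22 and Gclm at 1.69 ± 0.1. Lysosomal genes rose as groups: 20 of 43 hydrolases with 2 lower (Gla 0.77 ± 0.09, Ctsd 0.62 ± 0.08), 14 of 32 membrane and transport genes (Gpnmb 0.93 ± 0.11, Lamp1 0.47 ± 0.07) and 11 of 18 V-ATPase subunits (adjusted p = 0.00185, 0.000172 and 0.00154 with an estimated correlation). Cell cycle genes fell in 10 of 30 cases (Rrm2 -1.27 ± 0.18, Pcna -0.94 ± 0.15; adjusted p = 0.00328 with an estimated correlation), and MHC class II in 6 of 8 (H2-Ab1 -2.93 ± 0.28, H2-Eb1 -3.03 ± 0.33). Of 35 interferon-stimulated genes 12 rose and 2 fell (Rsad2 1.60 ± 0.29, Bst2 0.68 ± 0.13), a call lost with an estimated correlation (adjusted p = 0.243). Of 31 autophagy genes 6 rose and 2 fell (Sqstm1 0.94 ± 0.09; adjusted p = 0.33 with an estimated correlation). The targeted gene Pik3c3 is itself on the autophagy list and counts among the genes that fell there. The 3 stromal genes fell (Col1a1 -4.23 ± 0.63, 4 of 5 pairs), and Col1a1 lost its call without Rosa26 replicate 5. Of 3 erythroid genes Hbb-bs fell (-2.68 ± 0.6, adjusted p = 0.000618). The count was 450 in Regular libraries, of which a single Pik3c3 library is one side, and 466 in Low-input libraries alone. No interferon-stimulated gene was called in Regular libraries and 6 in Low-input libraries, while sterol calls numbered 17 and 16.

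Ctsd cells of day 13 had 1 higher and 23 lower genes. Besides Ctsd (-2.25 ± 0.08, adjusted p = 5.56e-36), Mirt1, a noncoding RNA gene, fell by 2.61 ± 0.4 (adjusted p = 2.94e-05), and Col1a1, Fstl1 and Col1a2, of which Col1a1 and Col1a2 are on the stromal list, changed by -6.93 ± 0.87, -5.80 ± 0.94 and -4.58 ± 0.84 (Col1a2 in 4 of 5 pairs), with Col1a1 at 0.173 ± 0.159 against 14.9 ± 27.9 CPM. The SD of Rosa26 cells there exceeds the mean, and the falls of Col1a1, Fstl1 and Col1a2 lost their calls without Rosa26 replicate 5. All 3 genes of the stromal list fell, a list call lost with an estimated correlation (adjusted p = 0.122). The only rise, of the HSP90 co-chaperone Ahsa1 by 0.38 ± 0.09 (adjusted p = 0.0486), was lost without any 1 of 7 libraries. No interferon-stimulated gene was called over all genes and 4 of 35 were lower when adjusted over the list alone (median -0.41; adjusted p = 0.133 with an estimated correlation). Unadjusted p was under 0.05 for 1155 genes, and DESeq2 called 13. The count was 3 without Rosa26 replicate 5, 15 without Ctsd replicate 1, 15 without Ctsd replicate 3 and 2 in Regular libraries. In Low-input libraries alone Rosa26 replicate 5 is the only control, so a count there cannot tell a Ctsd effect from that library.

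In Grn cells of day 13, 1505 genes rose and 1523 fell. Dio2 rose by 4.19 ± 0.17 (adjusted p = 1.9e-30) to 345 ± 40.6 from 19.3 ± 3.76 CPM, Cdkn1c by 3.32 ± 0.19, the phagocytosis bridge Mfge8 by 2.45 ± 0.18 and the stress gene Gadd45a by 2.22 ± 0.15. Of 23 lipid-associated macrophage genes 13 rose and 4 fell (adjusted p = 0.00628 with an estimated correlation), with the fatty acid binders Fabp4 and Fabp5 at 2.63 ± 0.2 and 2.26 ± 0.14, Gpnmb at 1.13 ± 0.11 and the tetraspanin Cd63 at 0.99 ± 0.09. V-ATPase subunits rose in 16 of 18 cases (18 adjusted over the list alone; Atp6v1c1 0.97 ± 0.08, Atp6v1h 0.88 ± 0.09), sterol genes in 19 of 24 (Sc5d 1.36 ± 0.1, Mvd 1.93 ± 0.17) and lysosomal hydrolases in 20 of 43 with 2 lower (Gla 1.19 ± 0.09, Ctsd 0.80 ± 0.07). With an estimated correlation the adjusted p-values of these lists were 1.02e-05, 0.000121 and 0.0261. Among 14 iron handling genes 4 rose and 1 fell, with the transferrin receptor Tfrc at 1.59 ± 0.09 (adjusted p = 2.19e-24) and the ferrireductase Steap3 at 0.99 ± 0.16 (adjusted p = 0.0106 for the list with an estimated correlation). Macrophage identity genes fell in 12 of 19 cases and rose in 1 (Cx3cr1 -2.63 ± 0.26, Adgre1 -0.79 ± 0.1; adjusted p = 1.61e-05 with an estimated correlation), 7 of 8 genes of the MHC class II presentation list fell (H2-Ab1 -1.40 ± 0.24, and the costimulatory gene Cd86 -1.16 ± 0.2), and Adgre4 fell by 3.02 ± 0.25. All 3 erythroid genes fell (Hba-a2 -3.50 ± 0.68, Hbb-bs -2.98 ± 0.54) and brain markers stood at 28.3 ± 1.72 against 132 ± 65.4 CPM in Rosa26 cells. With the brain-marker level as a covariate 1498 genes were called, 1388 of them in both fits, MHC class II calls fell to 3 and the erythroid calls to 0. All 3 stromal genes fell as well (Col1a1 -5.31 ± 0.78, 4 of 5 pairs), and 5 of 13 mitochondrially encoded messages fell (mt-Co1 -0.55 ± 0.11), a list call lost with an estimated correlation (adjusted p = 0.451). The count was 3120 in Regular and 598 in Low-input libraries alone.

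In Trem2 cells of day 13, 1361 genes rose and 1305 fell. F13a1 rose by 3.52 ± 0.25 (adjusted p = 1.3e-18) to 94.3 ± 25.2 from 7.44 ± 2.26 CPM, the sialic acid receptor Cd33 by 2.89 ± 0.2, the endothelin receptor Ednrb by 2.56 ± 0.22, the cytokine Tslp by 4.44 ± 0.55 and the lectin Cd209f by 7.15 ± 1.03, which DESeq2 did not call (adjusted p = 0.392). Of 23 lipid-associated macrophage genes 18 fell, the targeted gene Trem2 among them, and 3 rose (adjusted p = 8.98e-07 with an estimated correlation), with Itgax at -4.31 ± 0.21 (4.68 ± 1.3 against 66.6 ± 12.8 CPM), Mmp12 at -3.73 ± 0.19, Gpnmb at -1.56 ± 0.12 and lipoprotein lipase Lpl at -1.54 ± 0.15. Dcstamp and Mamdc2 fell (-4.09 ± 0.25 and -4.06 ± 0.23), and of 5 osteoclast markers, which include Dcstamp, 3 fell and 2 rose (adjusted p = 0.00299 with an estimated correlation). MHC class II fell in 7 of 8 genes, while the list's costimulatory gene Cd86, named after its value was seen, rose (H2-Ab1 -3.97 ± 0.32, Cd74 -3.60 ± 0.32; adjusted p = 0.000765 with an estimated correlation). Sterol genes fell in 13 of 24 cases (Srebf2 -1.28 ± 0.16, Sqle -1.51 ± 0.19), integrated stress response genes in 11 of 26 with 4 higher (Psat1 -1.67 ± 0.17, Mthfd2 -1.48 ± 0.15) and immediate early genes in 8 of 12 (Fos -1.90 ± 0.27, Dusp1 -1.43 ± 0.17, Zfp36 -1.40 ± 0.16). With an estimated correlation their adjusted p-values were 0.0294, 0.0126 and 0.00313. Macrophage identity genes rose in 10 of 19 cases and fell in 2 (Maf 0.92 ± 0.09, Mertk 1.27 ± 0.15, Mrc1 1.17 ± 0.14; adjusted p = 0.00236 with an estimated correlation), and Tfrc fell by 1.69 ± 0.1. Col1a1 fell by 3.21 ± 0.57 in 3 of 5 pairs and lost its call without Rosa26 replicate 5. Of 3 erythroid genes Hbb-bt fell (-2.75 ± 0.98, adjusted p = 0.0338), a call lost without Rosa26 replicate 2 or 5 or Trem2 replicate 1, 2, 3 or 5 (adjusted p between 0.0599 and 0.0757). All Trem2 libraries of this day are Low-input, so the comparison leans on the protocol term: without it 5388 genes were called, and Low-input libraries alone, with Rosa26 replicate 5 as the single control, gave 952. No Regular-only value exists. Without Rosa26 replicates 2 and 5, which leaves no Low-input Rosa26 library of this day, the count was 1657.

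**Figure D4:**
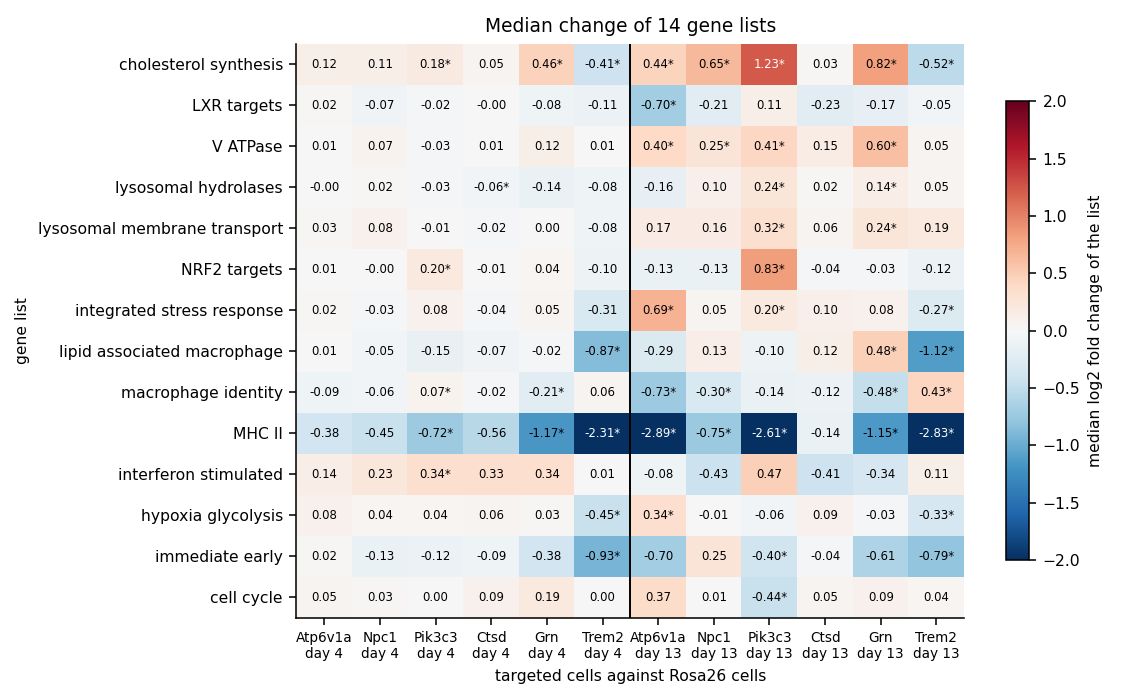
Median log2 fold change (colour and printed value) of 14 gene lists in targeted against Rosa26 cells by day; * marks lists with camera's adjusted p under 0.05 with an estimated correlation. The median of sterol genes was 1.23 in Pik3c3 and -0.52 in Trem2 cells of day 13, and that of MHC class II genes -2.89 in Atp6v1a and -2.83 in Trem2 cells.

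**Figure D5:**
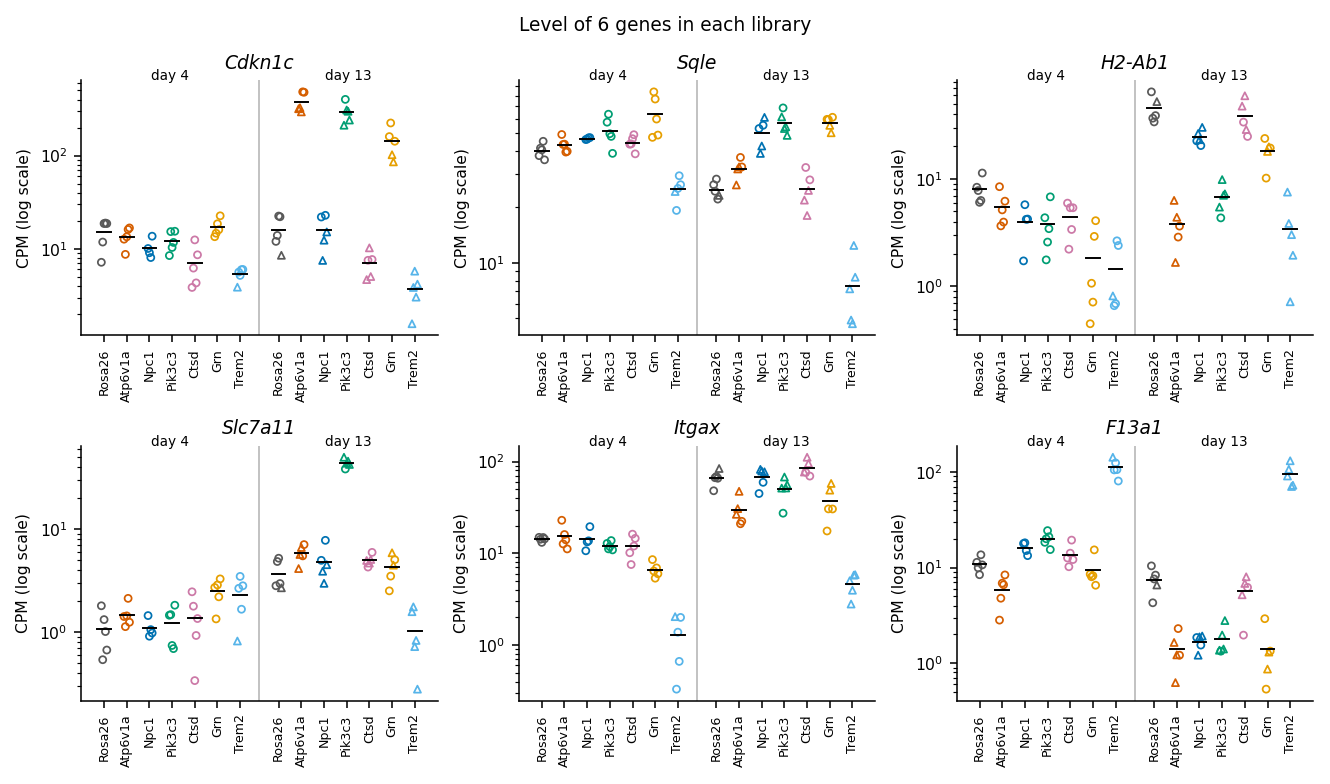
Level of 6 genes in CPM (log scale) in each library by target, with day 4 left and day 13 right of the grey line; circles are Regular and triangles Low-input libraries, and horizontal bars group means. Cdkn1c stood at 380, 292 and 143 CPM on average in Atp6v1a, Pik3c3 and Grn cells of day 13 against 15.8 in Rosa26 cells, and Itgax at 4.68 CPM in Trem2 cells of day 13 against 66.6.

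Whether an effect differed between days was tested as a difference of the 2 effects, given here as day 13 minus day 4. In Atp6v1a cells 668 genes had a higher and 698 a lower effect at day 13, among them Cdkn1c (5.06 ± 0.3, adjusted p = 9.41e-22), Dio2 (4.05 ± 0.28), Chac1 (3.42 ± 0.77), Ddit3 (2.11 ± 0.2) and H2-Eb1 (-3.98 ± 0.67). There 16 of 26 integrated stress response genes had a higher effect, 6 of 8 MHC class II genes a lower one, and macrophage identity genes a higher effect in 1 and a lower one in 11 of 19 cases (adjusted p = 4.3e-08, 0.000117 and 4.3e-08 with an estimated correlation). In Pik3c3 cells the effect was higher for 433 and lower for 310 genes, with Cdkn1c at 5.00 ± 0.31 (adjusted p = 8.45e-21), Ccl5 at 4.51 ± 0.72, Slc7a11 at 3.43 ± 0.52 and Mvd at 2.56 ± 0.24. Sterol genes had a higher effect in 16 of 24 cases and NRF2 targets in 7 of 16 with 1 lower (adjusted p = 7.05e-06 and 7.58e-05 with an estimated correlation), and Cx3cr1 differed by 2.16 ± 0.3, Mgl2 by -3.50 ± 0.44 and F13a1 by -3.01 ± 0.41. In Npc1 cells 10 genes had a higher and 14 a lower effect. Slamf8 (1.22 ± 0.22, adjusted p = 0.00181), Fabp4 (1.54 ± 0.31) and Sqle (0.89 ± 0.2) were higher, and Tgfbi (-1.55 ± 0.19, adjusted p = 1.98e-07), Mgl2 (-2.54 ± 0.41) and F13a1 (-2.75 ± 0.41) lower. Sterol genes differed in 4 of 24 cases (11 adjusted over the list alone; adjusted p = 0.00331 with an estimated correlation). The Npc1 count was 52 with the replicate block, 13 and 10 without Npc1 replicate 2 or 3 of day 4, and 10 in Regular libraries, where Sqle did not pass (adjusted p = 0.11). Sqle also lost its call (adjusted p between 0.0563 and 0.064) without Rosa26 replicate 4 of either day, Npc1 replicate 2 or 3 of day 4, or Npc1 replicate 5 of day 13. The Pik3c3 count was 243 in Regular libraries.

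Between days, Grn cells had 569 genes with a higher and 672 with a lower effect at day 13. Dio2 (3.97 ± 0.27, adjusted p = 3.5e-18), Cdkn1c (3.13 ± 0.29), Mfge8 (2.63 ± 0.26), Fabp4 (2.35 ± 0.29), Tfrc (1.45 ± 0.12), Cd63 (0.99 ± 0.12) and Ctsd (0.76 ± 0.1) had higher effects. Lysosomal hydrolases had a higher effect in 17 of 43 cases and a lower one in 1, and lipid-associated macrophage genes a higher one in 13 of 23 (adjusted p = 0.00185 and 0.00109 with an estimated correlation). Hba-a2 (-5.85 ± 0.83) and Hbb-bs (-5.34 ± 0.71) had lower effects along with the brain markers, whose level was above that of Rosa26 cells at day 4 and below it at day 13. With the brain-marker covariate 278 genes differed, 200 of them in both fits, with 10 hydrolases and 7 lipid-associated genes. In Trem2 cells 480 genes had a higher and 475 a lower effect, with Col4a2 at 2.88 ± 0.55, Tmem176b at 1.73 ± 0.21 (adjusted p = 1.78e-08), Serpine2 at -3.79 ± 0.43 and Tfrc at -1.55 ± 0.12, and 6 of 19 macrophage identity genes higher and 1 lower (adjusted p = 0.00778 with an estimated correlation). Erythroid genes had lower effects in all 3 cases, and Ndrg2 (-3.39 ± 0.46) was not called with the brain-marker covariate (-1.12, adjusted p = 0.071), when 633 genes differed. The Trem2 count was 592 without replicate 1 of day 4, the only Low-input library of that day. In Ctsd cells 1 gene differed, Ly6a, the stem cell antigen Sca-1, with a lower effect at day 13 (-4.69 ± 0.83) and adjusted p = 0.00436 (lower than Rosa26 in 5 of 5 pairs of day 13). Its adjusted p was 0.362 without Rosa26 replicate 5 of day 13. Trim12a (-1.13 ± 0.24) and Tarbp2 (0.73 ± 0.16), next by p, did not pass (both adjusted p = 0.0832) and passed with the replicate block (adjusted p = 0.0233 and 0.0406). None of 35 interferon-stimulated genes was called in Ctsd cells over all genes, yet 22 had a lower effect adjusted over the list alone (median -0.84; adjusted p = 0.0199 with an estimated correlation). The unadjusted p was under 0.05 for 1124 genes, DESeq2 called 4 and the replicate block 7. The count was 2, 2, 3, 0 and 2 without Rosa26 replicate 3 or Ctsd replicate 1 of day 4, Rosa26 replicate 2 or 5 or Ctsd replicate 1 of day 13.

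Rosa26 cells themselves changed between day 4 and day 13, with 1802 genes higher and 1872 lower at day 13. Cell cycle genes fell in 29 of 30 cases (adjusted p = 2.8e-15 with an estimated correlation), including Plk1 by -3.26 ± 0.19, Ccna2 by -2.95 ± 0.13 and Top2a by -2.46 ± 0.1 (adjusted p = 2.86e-30). The neutrophil granule genes S100a9 and S100a8 changed by -5.59 ± 0.58 and -2.64 ± 0.35, 2 of 3 lower genes among 5 neutrophil markers (adjusted p = 0.143 with an estimated correlation). Interferon-stimulated genes fell in 23 of 35 cases and rose in 1 (Irf7 -2.40 ± 0.25, Ifi27l2a -1.19 ± 0.13), and sterol genes fell in 14 of 24, both list calls lost with an estimated correlation (adjusted p = 0.319 and 0.111). MHC class II rose in 7 of 8 genes (H2-Eb1 3.16 ± 0.34, H2-Ab1 2.44 ± 0.26; adjusted p = 0.0501 with an estimated correlation), and Mmp12 and Itgax rose by 2.40 ± 0.17 and 2.07 ± 0.16. All 13 mitochondrially encoded messages rose (mt-Nd5 1.04 ± 0.11; adjusted p = 0.121 with an estimated correlation). Sparc (3.60 ± 0.54) rose with the other 2 stromal genes, which are high in replicates 2 and 5 of day 13, and all 3 erythroid genes rose (Hbb-bs 2.79 ± 0.46) along with brain markers (41.6 ± 14.8 to 132 ± 65.4 CPM). With the brain-marker covariate 2139 genes were called, 1915 of them in both fits, with 12 interferon-stimulated and 3 MHC class II genes, and without the protocol term 2191.

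Calls shared between targets were counted against the calls expected of independent lists and against unchanged groups that share the Rosa26 libraries. At day 13, Atp6v1a and Grn cells shared 679 higher and 680 lower genes, where independent lists would share 193 and 176, and their changes correlated across genes by 0.61, against 0.51 for unchanged groups with the same Rosa26 libraries and 0.43 observed with separate Rosa26 libraries. The covariance was 0.134 against a simulated 0.026. Atp6v1a and Pik3c3 cells shared 444 higher and 466 lower genes (independent 110 and 84.7), Pik3c3 and Grn cells 439 and 357 (107 and 93), and Npc1 and Grn cells 231 and 173 (40.7 and 26.8). Grn and Trem2 cells of day 4 shared 325 higher and 268 lower genes (60.8 and 55.6), with 53 in opposite directions, while at day 13 they had 647 genes in opposite directions, where independent lists would have 336.2. Both groups of day 4 also had raised brain markers. With separate Rosa26 libraries Atp6v1a and Grn cells of day 13 shared 323.6 higher and 366.4 lower genes (independent 82.6 and 84.6). Genes are not independent replicates. At day 13, 5 genes were lower in cells of all 6 targets, Col1a1, Fstl1, Col1a2, Bgn and Ly6a, of which Col1a1 and Col1a2 belong to the stromal list that was high in Rosa26 replicates 2 and 5. Among the 17 genes higher in cells of at least 5 targets were Rragd, Atp6v0d1, Bhlhe41 and Cd300lf. Within a target, 1195 Trem2 genes were called in the same direction at both days (independent lists 323) and 46 in opposite directions. Grn cells had 369 in the same direction (122) and 168 in opposite directions. No count for independent lists was set beside these opposite calls. The effects of the 2 days correlated by 0.45 in Trem2 cells but by -0.01 in Grn cells, so the same-direction count does not show that the Grn effect persisted as a whole.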

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

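Chosen after their results were seen were the library-protocol and target tests of the brain messages with the marker sum they use, both tests of the stromal messages, the shared-control test of the Grn and Trem2 changes, and the splits of the Ctsd comparisons; the other tests were written before.

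Messages abundant in brain, among them Kif5a (15.5, 20.5 and 19.2 against 4.29 CPM), were higher in Grn and Trem2 cells of day 4 and Rosa26 cells of day 13 than in Rosa26 cells of day 4. Library protocol as the whole cause is argued against by a 2.92-fold higher marker sum in Grn than in Rosa26 cells among Regular libraries of day 4, and the target as the whole cause by the 4 of 5 Rosa26 libraries of day 13 that lay above the highest of day 4, though for the Grn and Trem2 groups the target stays open. Of the counted markers 81% (17 of 21, all but Syn1, Npy, Uchl1 and Mag) were higher in all 3 groups, a thin margin over the 80% set beforehand. The markers were written down after other brain genes had been noticed, so this count extends the pattern to more genes. RNA or reads of brain tissue in these libraries may be a source, but the count cannot tell it from another. A total of 256 genes rose and 96 fell with the marker level, and of the 1241 genes whose Grn effect differed between days 200 were also called with that level as a covariate. That covariate partly follows the groups and so also removes effects of the groups, and how such messages entered the libraries was not tested.

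Stromal messages such as Col1a1 were lower in the cells of all 6 targets than in Rosa26 cells at day 13. A fall caused by each target stays open, since the medians of 5 of the 6 targets (0.31 to 1.13 mean log2 CPM) lay below all 5 Rosa26 libraries (4.6 and 6.25 in replicates 2 and 5, 1.49 to 1.73 in the others), whereas the median of Trem2 cells, 2.93 with libraries from 0.19 to 4.18, lay above 3 of them. These levels had the protocol effect removed, so those of Low-input libraries, all Trem2 libraries among them, depend on its estimate. Among Regular libraries 5 of 10 targeted libraries, none of them Grn, were not below the lowest Rosa26 library. Library protocol may therefore still enter this comparison. RNA of other cells in Rosa26 replicates 2 and 5 may also account for it: without them 3 of the 24 Ctsd calls were made, against a median of 24 and a range of 3 to 34 over the other pairs of Rosa26 libraries left out. Every pair that includes replicate 5 gave 3, so this count speaks to that library alone, which is also the only Low-input Rosa26 library of the day, and whether such RNA came from stromal cells in the cultures was not tested.

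At day 13, 647 genes changed in opposite directions in Grn and Trem2 cells. Among Low-input libraries alone (2 Grn, 5 Trem2), all (100%) kept the sign of the Grn minus Trem2 difference, with a median of 1.23 against 1.25 in all libraries. Those libraries also helped to choose the genes, and 87.7% of all genes kept their sign. The difference holds no Rosa26 library, and all Trem2 but only 1 Rosa26 library of that day were Low-input. It therefore cannot decide whether library protocol set the 2 targets on opposite sides of Rosa26 cells. With separate Rosa26 libraries 395.7 opposite calls were made, where independent lists would have 150, which decides nothing on the shared libraries, since unchanged groups that share them correlated by 0.5 and so move the same way. A biological difference between the targets, which the design names, may explain the pattern and stays a hypothesis, since it was found and tested on the same data. With Trem2 the counts were 584 for Atp6v1a (independent 324.6; 376.6 against 156.6 with separate Rosa26 libraries), 208 for Npc1 (59.2; 92.5 against 16.6), 217 for Pik3c3 (175.9; 141.2 against 80.6) and 2 for Ctsd (2.7; 0.4 against 0.9), and no explanation was tested for these pairs.

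Several single libraries lay far from the rest of their group by Dixon's gap test. Among totals, Trem2 replicate 1 of day 4 had 4688000 counts (the others 2513000 to 3047000). The protocol-adjusted log2 level of Grn was 11.15 in Rosa26 replicate 1 of day 13 (11.48 to 11.6), and that of Trem2 was 8.98 in Rosa26 replicate 1 of day 4 (8.602 to 8.683). The list means on the same scale were 1.671 for neutrophil markers in Npc1 replicate 2 of day 4 (2.365 to 2.405), 2.114 for stromal markers in Trem2 replicate 5 of day 4 (1.626 to 1.762), 1.772 for the mast cell gene Kit in Atp6v1a replicate 1 of day 4 (0.4733 to 0.7982), 1.239 for Kit in Pik3c3 replicate 2 of day 4 (-0.2565 to 0.0691) and 9.64 for mitochondrial messages in Atp6v1a replicate 1 of day 13 (9.177 to 9.257). Chance marks about 1 in 20 groups. Of 14 groups tested for totals 1 was beyond the limit (0.7 by chance), of 24 for targeted genes 2 (1.2) and of 70 for the lists 5 (3.5).

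Effects that differed between days by a test of the difference numbered 1366 genes for Atp6v1a, 24 for Npc1, 743 for Pik3c3, 1 for Ctsd, 1241 for Grn and 955 for Trem2. The effect on the targeted gene itself differed by 0.39 for Atp6v1a and by 0.88 for Trem2.

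Each count was set beside 100 splits of the same libraries into groups of the same sizes, the real split included. The scaling and stored dispersions of the full fit were reused. The quasi-likelihood fit, which sets the gene-wise spread of the test, was made anew for each split. For differences between days the split of day 13 was also turned round at random. For the Ctsd difference between days 5 splits gave at least 1 call (highest other 1), so chance could not be excluded there. For Npc1 at day 4, 26 splits gave at least the real 1 call (highest other 2). That call is the targeted gene itself (adjusted p = 1.23e-08 in edgeR's test), so a count of 1 cannot decide on chance for it. For Atp6v1a at day 4, 3 splits reached the real 1 call (highest other 2), which is again the targeted gene, so this count cannot decide either. For Ctsd at day 4 only 1 split, the real one, reached its 15 calls (highest other 2). For Pik3c3 at day 4, 3 splits reached the 21 calls and the highest other called 127, several times as many. What sets that split apart was not tested. At day 4 the real split alone was as large for Grn (966, highest other 296) and Trem2 (2912, highest other 1441). At day 13 this held for Atp6v1a (2927, highest other 1633), Npc1 (536 and 83), Pik3c3 (1587 and 413), Grn (3028 and 1936) and Trem2 (2666 and 644), while for Ctsd 2 splits reached 24 calls (highest other 38). Of the differences between days, the real split alone was as large for Atp6v1a (1366, highest other 219), Npc1 (24 and 8) and Pik3c3 (743 and 29), 2 splits were for Grn (1241 and 1504) and 3 for Trem2 (955 and 1357). For Rosa26 cells over time it was the real split alone (3674, highest other 2274). The real split parts all same-numbered pairs, which share a marrow pool, while most other splits keep some pairs together and so set pools against each other. Among the 10 to 14 other splits that part as many pairs, none was as large against Rosa26 cells or over time except 1 of 14 for Pik3c3 at day 4 (36 calls). For Npc1 at day 4 it was 0 of 10 (highest 0) and for Ctsd at day 13 0 of 12 (highest 6). These splits, and the 0 to 3 of the differences between days, are too few for a share under 0.05.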

How the results depend on the processing

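Low-input libraries only, the fit without Rosa26 replicates 2 and 5 of day 13 and the brain-marker covariate were chosen after the data were seen; the other settings were planned. Of 264 named-gene values, 259 were called. Of these, 211 stayed past the threshold in every planned setting other than the leave-outs. Those settings include Regular libraries only and each day fitted separately, and a setting that gave no value for a gene was passed over. Without any 1 library 232 stayed past it, and without any 1 replicate number 217. No value lost its call with the replicate block and 2 gained it (Trim12a and Tarbp2 between days in Ctsd cells), 1 of 264 lost it with RLE size factors, 4 of 261 with DESeq2, 5 of 264 without a filter, 10 of 211 with each day fitted separately, 28 of 264 without the protocol term, 24 of 229 in Regular and 22 of 132 in Low-input libraries. With the brain-marker covariate 16 of 264 did and without Rosa26 replicates 2 and 5 of day 13 18 did with their direction kept and 4 more reversed. These 4 did not pass: Col1a1 at day 13 in Pik3c3 cells (1.45, adjusted p = 0.63), in Grn cells (0.08, adjusted p = 0.983) and in Trem2 cells (2.59, adjusted p = 0.249), and Col1a2 in Ctsd cells (0.4, adjusted p = 0.967), where the libraries left out are those that hold these messages. The p53 list, which went both ways at day 13, turned to more higher genes in Atp6v1a cells (3 of 4 calls without a filter, 3 of 5 in Regular and 3 of 4 in Low-input libraries) and to more lower ones in Grn cells (3 of 5 with each day fitted separately and without replicate 2 or 5). Of 112 list tests of the text, 21 lost their call with an estimated correlation, and with fry 3 lost and 12 gained it. The number of called list members moved by over 1.5 times, or to or from 0, in 0 of 112 cases with RLE size factors. It did so in 6 with DESeq2, 12 with the replicate block, 20 without the protocol term and 22 with the brain-marker covariate. In Regular libraries 23 of 98 moved and in Low-input libraries 56 of 67. Depth limits genes with few counts, where removing the filter added genes and moved counts.

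The counts of calls moved by over 1.5 times as follows; where fewer libraries entered that alone lowers counts, and other causes were not tested. By DESeq2 at day 4, Atp6v1a gave 5 (2 higher, 3 lower), Npc1 3 (2 higher, 1 lower), Pik3c3 34 and Ctsd 29, and Ctsd gave 13 at day 13 (2 higher, 11 lower) and 4 between days. In Regular libraries only, Npc1 gave 2 at day 4 and 101 at day 13, Pik3c3 450 and Ctsd 2 at day 13, and between days Npc1 gave 10, Pik3c3 243 and Ctsd 0; there 10 of 11 targeted-gene values passed, and no value for Trem2 at day 13 or between days could be had. In Low-input libraries only, day 13 counts were 977 for Atp6v1a, 82 for Npc1, 466 for Pik3c3, 48 for Ctsd, 598 for Grn and 952 for Trem2, each against 1 Rosa26 library assumed to vary like the others, and 5 of 6 targeted-gene values passed. With each day fitted separately Ctsd gave 7 at day 4 and 15 at day 13. Without a filter Atp6v1a, Npc1, Pik3c3 and Ctsd gave 19, 22, 55 and 81 at day 4, Ctsd 132 at day 13, and between days Npc1 86 and Ctsd 101. Without the protocol term the counts were 6 for Pik3c3, 4 for Ctsd and 300 for Grn at day 4. All libraries of these groups and of Rosa26 cells of day 4 are Regular. There the term can act only through the spread that all groups share. Also without it, the counts were 3280 for Pik3c3 and 5388 for Trem2 at day 13. Between days they were 15 for Npc1, 0 for Ctsd, 777 for Grn and 1744 for Trem2, and 2191 for Rosa26 over time. With the replicate block, which uses the shared marrow pools, Pik3c3 gave 42 and Ctsd 34 at day 4, Npc1 52 and Ctsd 7 between days, and no other count moved so far. With the brain-marker covariate Trem2 gave 1922 at day 4, Npc1 341 and Grn 1498 at day 13, Ctsd 2, Grn 278 and Trem2 633 between days, and Rosa26 over time 2139. Without the 2 Rosa26 libraries Ctsd gave 3 and Trem2 1657 at day 13, and Ctsd 3 between days. RLE moved no count that far. With the Rosa26 libraries split, shared calls fell from 1359 to 690 for Atp6v1a and Grn, from 910 to 504 for Atp6v1a and Pik3c3, from 796 to 388.5 for Pik3c3 and Grn, and from 593 to 206.2 for Grn and Trem2 at day 4, and opposite calls of Grn and Trem2 from 647 to 395.7. Fewer controls lower the calls of each target as well: in the same order independent lists would share 82.6 higher and 84.6 lower genes (193 and 176 with all controls), 48.2 and 41.2 (110 and 84.7), 45 and 40.5 (107 and 93) and 16.3 and 17.2 (60.8 and 55.6), and have 150 opposite calls (336.2). List tests past the threshold fell from 190 to 105 of 513 with an estimated correlation. No library met the planned exclusion of shallow libraries, so that setting gave no value.

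Leaving out single libraries or replicate numbers gave at day 4 between 1 and 2 calls for Atp6v1a, 1 and 1 for Npc1, 5 and 43 for Pik3c3, 3 and 21 for Ctsd, 377 and 1147 for Grn and 2111 and 2991 for Trem2. At day 13 the ranges were 2144 to 2883, 161 to 636, 1068 to 1725, 3 to 28, 2196 to 3164 and 1770 to 2680 in the same order, and between days 827 to 1416, 4 to 40, 374 to 1086, 0 to 3, 572 to 1887 and 430 to 1064. Rosa26 over time ran from 2660 to 4147. Genes called in every fit without 1 library numbered 1, 1, 7, 4, 410 and 1949 at day 4, 1888, 197, 958, 3, 1847 and 1622 at day 13, and 2466 for Rosa26 over time. Among single libraries, 629 Grn calls of day 4 were left without Grn replicate 3, and 353 and 318 Npc1 calls of day 13 without Rosa26 replicate 4 or Npc1 replicate 5. The other single libraries that moved a count this far are named beside the results.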

Other observations

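All tests in this part were chosen by the fixed lists except the 3 genes that follow Ctsd, which were picked after their values were seen. Gdf15, a stress cytokine among 19 p53 targets, rose by 1.36 ± 0.19 in Grn cells of day 4 and by 1.94 ± 0.21, 2.61 ± 0.22 and 1.89 ± 0.21 in Atp6v1a, Pik3c3 and Grn cells of day 13. In Trem2 cells of day 4 the p53 list had 8 higher and 2 lower genes (Trp53inp1 1.14 ± 0.15, Ccng1 0.78 ± 0.11, Plk2 -1.23 ± 0.16; adjusted p = 0.0291 with an estimated correlation), and at day 13 of Atp6v1a, Pik3c3 and Grn cells it moved both ways (adjusted p = 0.726, 0.358 and 0.604). At day 13 Tfrc rose by 1.29 ± 0.09 in Pik3c3 cells, where 4 of 14 iron genes rose and 2 fell (adjusted p = 0.00222 with an estimated correlation), and in Atp6v1a cells 2 rose and 6 fell, with the iron exporter Slc40a1 at -1.95 ± 0.25 and haem oxygenase Hmox1 at -0.97 ± 0.11 (adjusted p = 0.068); a difference between these targets was not tested. TFEB and nutrient-sensing genes rose in 2 of 14 cases in Npc1, 5 in Pik3c3 and 5 in Grn cells of day 13, with 0, 1 and 1 lower (adjusted p = 0.000965, 0.000432 and 0.00775 with an estimated correlation), and Rragd rose by 1.23 ± 0.13 in Pik3c3 cells.

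Of 31 autophagy genes 10 rose and 2 fell in Grn and 8 rose in Trem2 cells of day 13 (adjusted p = 0.451 and 0.288 with an estimated correlation). Of 19 NF-kB genes 4 fell in Trem2 cells of day 4 (adjusted p = 0.0322), and at day 13 3 rose and 6 fell in Atp6v1a, Grn and Trem2 cells alike (adjusted p = 0.15, 0.229 and 0.278). In Pik3c3 cells of day 13 Dcstamp fell by 2.34 ± 0.2 and Cx3cr1, lower in Npc1 and Grn cells, rose by 1.75 ± 0.21. Osteoclast markers, of which 5 were tested, fell in 3 cases in Grn cells of day 4 (adjusted p = 0.00165 with an estimated correlation). The mast cell gene Kit rose in Atp6v1a, Pik3c3 and Grn cells of day 13 (3.11, 1.78 and 1.56, the last in 4 of 5 pairs), and in none of the 12 comparisons with Rosa26 cells did over 1 of the 5 neutrophil markers rise or any fall.

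In Ctsd cells 3 genes of low level were lower at both days. Olfr46 stood at 1.19 ± 0.752 against 5.35 ± 0.725 CPM in Rosa26 cells at day 4 and 1.9 ± 1.04 against 7.4 ± 1.94 at day 13, Mirt1 at 0.54 ± 0.703 against 4.94 ± 1.52 and 1.13 ± 0.413 against 6.43 ± 1.59, and Serpinc1 at 0.46 ± 0.407 against 2.59 ± 0.625 and 0.817 ± 0.467 against 3.37 ± 0.997 (n = 5 each). None of the 3 (0) shares a 31-base word with a Ctsd transcript in GRCm38. Olfr46 lies on the same chromosome as Ctsd there, though not close to it, and Mirt1 and Serpinc1 lie on other chromosomes. What lowers the 3 genes was not tested further.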
